A study of Homo sapiens with 24 samples.

How the data were processed

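The data are RNA sequencing of the human ovarian cancer cell line ES-2 in 24 libraries, 6 for each of 4 groups. Per the labels the groups are control, elesclomol, olaparib and elesclomol with olaparib, the cells were grown in RPMI-1640 medium with 10% fetal bovine serum, total RNA was extracted with TRIzol, and libraries were read on an Illumina instrument. Doses and durations are not given. The authors deposited 1 table with a column of counts and a column of FPKM for every library. The counts are whole numbers per gene without normalization, per the file headers and the values. The FPKM, per the file headers, are the counts scaled by the authors by a gene length that the table does not print and by the column total. This was checked: after rescaling by the column totals, the ratio of FPKM to count equalled the gene's median ratio within a relative tolerance of 0.0001 for 100.0% of the values above 0. HISAT2, DESeq and the genome build GRCh38 are named in the submitters' processing notes, without versions, order or role. The counter, the annotation release, any filter and the handling of strands are not stated, so reads of genes that overlap on opposite strands may be counted for either gene. Only the counts were used here.

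The table held 38681 genes, of which 27907 carry a symbol in the table, 10716 were named from GENCODE release 29 by their Ensembl identifier and 58 have no symbol. Positions are those of GENCODE release 29 on GRCh38, which holds 37319 of the genes. Every value column was assigned to a library by its header, and 0 columns were left over. Total counts ranged from 14793908 to 31468678 per library. The common biological coefficient of variation was 14.47%. Tested on simulated data with 200 genes changed per effect, 61.2% of 1.5-fold and 87.8% of 2-fold changes between elesclomol and control were found, and 34.0% and 68% of those in the interaction. Of the calls in simulated data 4.04% to 8.41% were false, depending on the comparison, and 0 had the wrong direction. A planted list of 21 genes with a 1.5-fold shift was found in the comparisons that held it. The simulated genes varied independently, while in the data 1 principal component held 47.5% of the variance within groups. For both drugs against control 447 genes were called in the simulation and 11717 in the data. The simulated shares need therefore not hold for the data, nor does the planted list show how lists of correlated genes fare.

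Genes with low counts were removed with edgeR's filterByExpr, which left 15904 genes. Libraries were scaled by TMM, and all 24 were fitted together with 1 mean per group by the robust quasi-likelihood method of edgeR 4.0.16 in R 4.3.3. P values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, and genes with an adjusted p under 0.05 were called. In all, 7 comparisons were made: each drug group with control, the combination with each drug, elesclomol with olaparib, and the interaction, which is the combination minus elesclomol minus olaparib plus control on the log2 scale. CPM values use the TMM-scaled totals.

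Before the data were examined, 33 gene lists with 825 members, 20 genes bearing on the study's subject, the rule for naming genes, the comparisons and the alternatives were fixed. Of the members 818 were in the table and 740 were tested. Lists with at least 3 tested members, 32 of the 33, were tested against all other genes with camera from limma 3.58.1, with the preset correlation of 0.01 between genes and, as an alternative, a correlation estimated per list. The genes named are the 6 highest and 6 lowest log2 changes in each comparison with control and the 4 highest and 4 lowest in the others. They needed an adjusted p under 0.05, a mean CPM of at least 2, a named symbol and, in pairwise comparisons, every library of one group beyond all of the other. Up to 3 members of each list with the smallest adjusted p and the 20 genes fixed beforehand were added; some genes that the rule names are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

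The share of counts from the 37 mitochondrial genes was compared with control by an exact two-sided permutation test. Where a group had 0 counts for a gene, the fold is a bound against a floor of 3 counts over the group. GC content was available for 15734 of the tested genes. The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter and a stricter filter of a mean CPM of at least 1, only the compared groups in the fit, the replicate number as a block, each library left out in turn, controls split between comparisons for the overlap, and other denominators and genes for the mitochondrial share. A covariate for GC content and a fit without the 2 libraries that stood apart were added after the data were seen. The number of genes and lists found was also counted in 100 random regroupings of the libraries, the real grouping included. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used for the tables and figures.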

Results

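RNA was sequenced from 24 libraries of ES-2, a human ovarian cancer cell line, in 4 groups of 6. The groups are control cells, cells with elesclomol, cells with olaparib and cells with both drugs, called the combination here. Elesclomol is a small molecule that carries copper into cells, and olaparib inhibits the PARP enzymes, which act in the repair of DNA breaks. The labels give no dose and no duration, and they name treatments while the series text speaks of cells adapted to drugs. The total count per library ranged from 14793908 to 31468678, and 15904 of the 38681 genes in the table had enough counts to be tested. Changes are log2 fold changes ± SE with 6 libraries per group, and adjusted p values are from edgeR quasi-likelihood tests with Benjamini-Hochberg correction over all genes tested. Levels are means as CPM, counts scaled to library size, ± SD with 6 libraries, and positions are on GRCh38. Nothing in the labels says that the replicates are separate cultures, so the p values measure only the spread between these samples. Olaparib replicate 6 and combination replicate 2 stood apart from their groups: their distances to the mean of their own group were 0.642 and 0.679, against at most 0.351 for any other library.

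The comparison of elesclomol with control describes cells that had the copper carrier alone. TFRC, which encodes the transferrin receptor for iron uptake (ENSG00000072274, chromosome 3, 196027183 to 196082189), rose from 59.4 ± 1.96 to 325 ± 11.8 CPM, a change of 2.45 ± 0.07 (adjusted p = 5.9e-18). The chemokine genes CXCL1 and CXCL8 rose by 2.45 ± 0.09 and 2.42 ± 0.16, and CCNE2, which encodes a cyclin of S-phase entry, rose by 2.60 ± 0.24. CLDN2, a claudin gene of tight junctions (ENSG00000165376, chromosome X, 106900164 to 106930861), fell from 563 counts over the 6 control libraries to 9 over the 6 elesclomol libraries. MAPT, the gene of the microtubule-binding protein tau, fell by 2.56 ± 0.16, and TAGLN, which encodes an actin-binding protein, fell by 2.15 ± 0.18. Exons of CCNE2, CLDN2, MAPT and TAGLN, and those of ESM1, MANCR and MT1X, overlap those of neighbouring genes, and the handling of strands is not stated, so some of their counts could not be assigned with certainty.

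Genes of DNA synthesis rose together with elesclomol. Of the 38 DNA replication genes tested, 33 rose, 0 fell and 5 were not called. The median change was 0.72 (adjusted p = 5.5e-33 by camera, a test of a list against all other genes, and adjusted p = 3.7e-07 with an estimated correlation). GINS2, CDC6 and MCM10, which load or activate the replicative helicase, rose by 1.41 ± 0.06, 1.44 ± 0.07 and 1.90 ± 0.10. In the list of G2/M and mitosis genes 26 of 32 rose and 0 fell (adjusted p = 0.016 with an estimated correlation), among them MYBL2, a transcription factor gene of proliferating cells, with 1.81 ± 0.14. In ATR-CHK1 signalling 14 of 22 rose and 0 fell (adjusted p = 0.043 with an estimated correlation), led by TIMELESS with 0.87 ± 0.04 and CLSPN with 1.90 ± 0.11, both of which act at stalled replication forks. ATR, the kinase gene of this pathway, rose by 0.34 ± 0.11 (adjusted p = 0.024, but 0.0523 with upper-quartile scaling and 0.0534 or 0.0583 without control replicate 1 or 4), and CHEK1, which encodes the kinase that ATR activates, rose by 0.62 ± 0.15 (adjusted p = 0.0020). Of 22 Fanconi anaemia genes, which act in the repair of DNA crosslinks, 8 rose and 0 fell (adjusted p = 0.016 with an estimated correlation), with FANCA at 1.11 ± 0.08. Of 29 homologous recombination genes 13 rose and 1 fell, but the list was not past the threshold with an estimated correlation (adjusted p = 0.16). BRCA1, a gene of this pathway, rose by 0.94 ± 0.13.

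Inflammatory genes rose and amino acid stress genes fell with elesclomol. In the list of NF-kB targets and cytokines 14 of 23 rose and 1 fell (adjusted p = 1.8e-04 with an estimated correlation), including TNFAIP3, a feedback inhibitor of NF-kB, with 1.36 ± 0.07 and the cytokine gene IL24 with 1.86 ± 0.12. Of 27 genes of the integrated stress response, the programme of the transcription factor ATF4, 18 fell and 2 rose (adjusted p = 0.016 with an estimated correlation). CHAC1, which encodes a glutathione-degrading enzyme, fell by 2.03 ± 0.16, and SESN2, a stress-induced inhibitor of mTORC1, fell by 1.51 ± 0.10. Of 26 genes of cholesterol synthesis and uptake 15 fell and 1 rose (adjusted p = 0.015 with an estimated correlation). FDFT1, the squalene synthase gene, fell by 0.64 ± 0.04, and ACAT2 was the member that rose. Of 21 heat shock genes 14 rose and 0 fell (adjusted p = 0.042 with an estimated correlation), with HSPH1 at 0.98 ± 0.10; with upper-quartile scaling 9 rose.

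Metal and respiratory chain genes also changed with elesclomol. Of the 5 tested metallothionein and metal-induced genes 4 rose (adjusted p = 0.16 with an estimated correlation): MT1X, MT1E and MT2A, which encode metal-binding proteins, by 0.91 ± 0.24, 0.74 ± 0.12 and 0.64 ± 0.14. The metallothionein gene MT1G had 0 counts in the 6 control libraries and 120 in the elesclomol libraries, at least 37.4-fold higher against a floor of 3 counts over the group. SLC31A1, the main copper importer, fell by 0.52 ± 0.05, and ATP7B, a copper exporter, fell by 0.50 ± 0.09, but their list, copper handling, was not past the threshold, with 1 of 17 genes higher and 6 lower (adjusted p = 0.14). Of the 13 mRNAs of the mitochondrial genome 12 rose and 0 fell (adjusted p = 0.0098 with an estimated correlation), with MT-ND1, a complex I subunit, at 1.40 ± 0.07. Mitochondrial genes held 5.15% ± 0.14 of the counts with elesclomol and 4.45% ± 0.23 in control (SD, n = 6 each; exact permutation test, two-sided, p = 0.00216, the smallest possible, adjusted p = 0.00325), and all 6 elesclomol libraries lay above all 6 control libraries. This total mixes parts that moved apart: the protein-coding genes held 4.63% ± 0.10 with elesclomol and 3.33% ± 0.06 in control, and the mitochondrial rRNA genes 0.497% ± 0.0515 and 1.11% ± 0.24. The rRNA part was 1.71% ± 0.42 with olaparib and 0.775% ± 0.154 in the combination, and it was not tested. In the mesenchymal and extracellular matrix list 12 of 31 rose and 5 fell, which was not past the threshold with an estimated correlation (adjusted p = 0.54).

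In total 2899 genes were higher and 2866 lower with elesclomol, of which 294 and 380 changed at least 2-fold. With a covariate for GC content, chosen after the data were seen, 4899 were higher and 4746 lower. Camera passed 12 of 32 lists with its preset correlation and 9 with an estimated one. Adjusted over the list alone, 34 DNA replication, 28 G2/M and mitosis and 17 heat shock genes rose and 21 genes of the integrated stress response fell. In all comparisons but the interaction, random regroupings of the libraries often passed as many lists. Many of these regroupings still hold part of the drug difference, so they cannot decide whether chance gives as many lists. The p with an estimated correlation is given for each list past the threshold with the preset one.

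**Figure D1:**
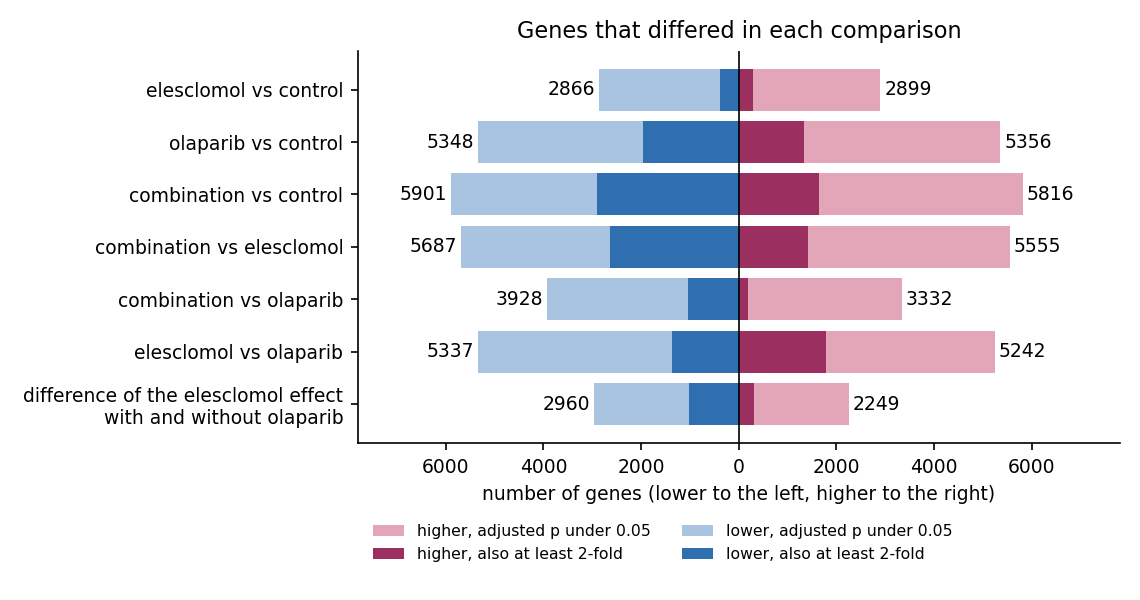
The bars give the number of genes higher (right) and lower (left) at an adjusted p under 0.05 in each of the 7 comparisons, with the dark part for changes of at least 2-fold. The comparison of the combination with control has 5816 genes higher and 5901 lower, and that of elesclomol with control 2899 and 2866.

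The comparison of olaparib with control describes cells that had the PARP inhibitor alone. SIPA1L2, which encodes a GTPase-activating protein (ENSG00000116991, chromosome 1, 232397965 to 232561558), rose from 1.06 ± 0.26 to 21.0 ± 1.57 CPM, a change of 4.30 ± 0.13 (adjusted p = 1.6e-18). GDF15, a stress-induced secreted factor, rose by 3.79 ± 0.27, PTGES, a prostaglandin E synthase, by 3.80 ± 0.20 and ARC, an immediate-early gene, by 3.79 ± 0.25. ESM1, which encodes a secreted proteoglycan (ENSG00000164283, chromosome 5, 54977864 to 55022671), fell from 144 ± 6.04 to 10.6 ± 1.18 CPM, a change of -3.78 ± 0.06 (adjusted p = 3.8e-23). HCAR1, the lactate receptor gene, fell by 4.85 ± 0.17. CDKN1A, the gene of the cell cycle inhibitor p21, rose by 2.74 ± 0.12 with olaparib (adjusted p = 1.3e-15), and ABCB1, which encodes the drug efflux pump P-glycoprotein, rose by 1.84 ± 0.13 (adjusted p = 1.1e-11).

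With olaparib 33 of 38 DNA replication genes rose and 1 fell, with a median of 0.87 (adjusted p = 2.5e-04 with an estimated correlation). ORC1 and CDC6, which mark and load replication origins, rose by 1.59 ± 0.05 and 1.75 ± 0.07. The other 5 lists past the threshold with the preset correlation were not past it with an estimated one. In ATR-CHK1 signalling 14 of 22 rose and 1 fell (adjusted p = 0.45 with an estimated correlation). CHEK1 rose by 1.18 ± 0.15 while ATR fell by 0.59 ± 0.12. In G2/M and mitosis 21 of 32 rose and 2 fell (adjusted p = 0.76 with an estimated correlation), with MYBL2 at 2.97 ± 0.14. All 5 metallothionein and metal-induced genes rose (adjusted p = 0.42 with an estimated correlation), with MT1X at 2.46 ± 0.21 and the zinc exporter gene SLC30A1 at 0.99 ± 0.07. In autophagy and lysosome 17 of 28 rose and 2 fell (adjusted p = 0.052 with an estimated correlation), with GABARAPL1, a gene of autophagosome membranes, at 0.70 ± 0.05. Of the mitochondrial mRNAs 10 of 13 fell and 1 rose (adjusted p = 0.62 with an estimated correlation; with the preset one the list was also lost without olaparib replicate 4 or 6, at 0.0583 and 0.0522). MT-CYB, of complex III, fell by 1.38 ± 0.06, and MT-CO1, of complex IV, rose by 0.58 ± 0.04. The mitochondrial share of counts, 4.94% ± 0.62 (SD, n = 6), differed from control by less than the test could separate (exact permutation test, two-sided, p = 0.0931), with 4 of 6 libraries above all controls and 1 below.

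Of the repair genes named beforehand, BRCA1 rose by 0.67 ± 0.13 and PARP1, the main target of olaparib, by 0.53 ± 0.04. PARP2 and SLFN11, which encodes a protein that blocks stalled forks, were not called, at -0.08 ± 0.11 and -0.22 ± 0.13. SLFN11 was called lower with upper-quartile scaling (adjusted p = 0.0315) and with a covariate for GC content chosen after the data were seen (2.7e-06), and PARP2 with that covariate (0.0067). In total 5356 genes were higher and 5348 lower with olaparib, of which 1343 and 1952 changed at least 2-fold. Adjusted over the list alone, 33 DNA replication and 18 autophagy and lysosome genes rose. HIF1A-AS3, RNVU1-24, RNVU1-26 and TRBV12-4 were also among the 6 highest or 6 lowest genes, at 4.07 ± 0.24, -4.15 ± 0.12, -3.97 ± 0.23 and -3.99 ± 0.16, but reads of such antisense and repeated genes are hard to assign.

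**Figure D2:**
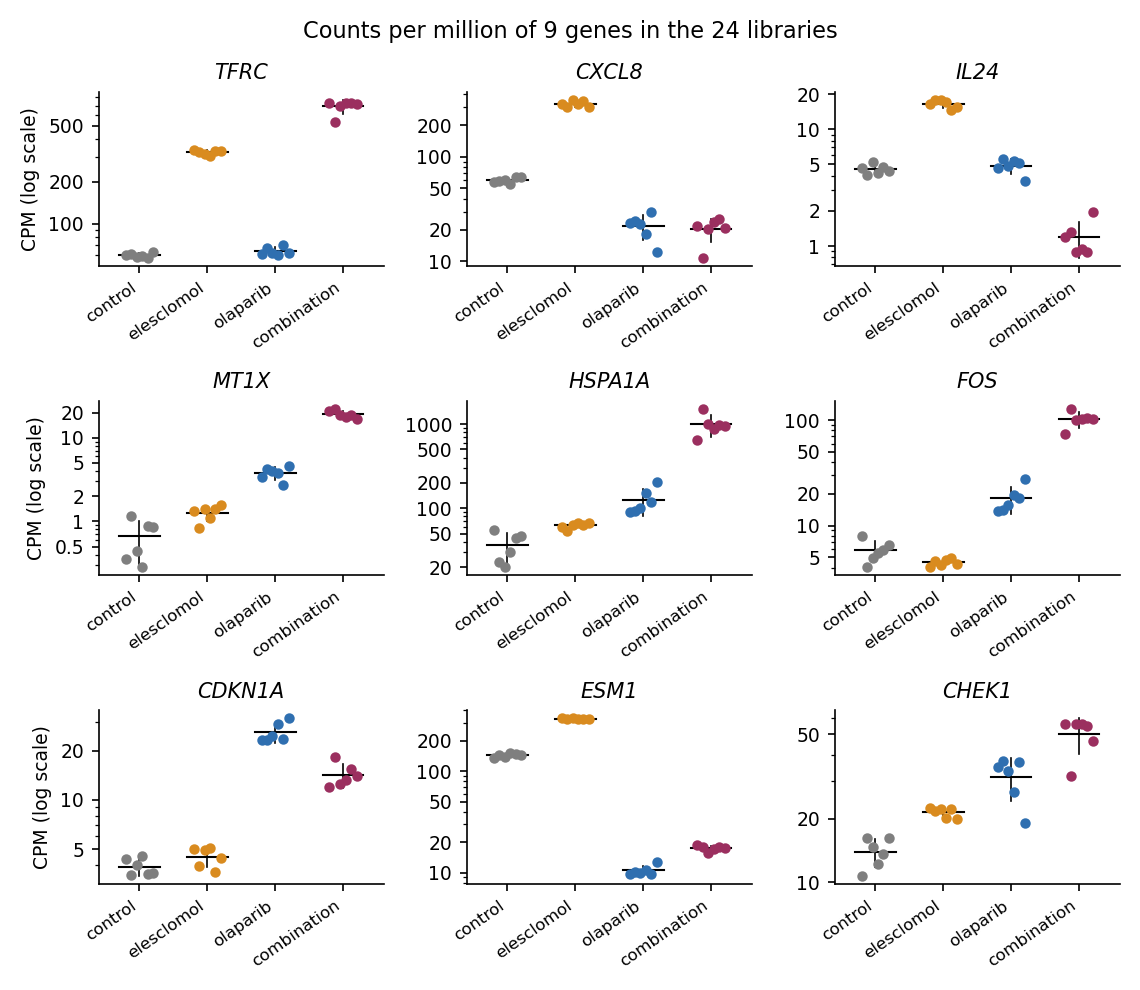
Each point is 1 of the 24 libraries and gives the CPM of a gene on a log axis, by group, with the mean as a horizontal line and the SD as a vertical one (n = 6). TFRC averages 59.4 CPM in control, 325 with elesclomol, 63.4 with olaparib and 689 in the combination.

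The comparison of the combination with control describes cells that had both drugs. TFRC rose by 3.54 ± 0.07, to 689 ± 78.5 CPM. MT1X, a metallothionein gene (ENSG00000187193, chromosome 16, 56682424 to 56684196), rose from 0.661 ± 0.351 to 19.2 ± 1.88 CPM, a change of 4.82 ± 0.19 (adjusted p = 1.9e-16), and HSPA1A, an inducible HSP70 gene, rose by 4.76 ± 0.27 (adjusted p = 8.4e-14). The replication-dependent histone gene H2AC8 rose by 4.55 ± 0.23, from a low level of 0.235 ± 0.0757 to 5.71 ± 0.578 CPM. MT1X, HSPA1A and H2AC8 belong to families with near-identical copies, so reads may be shared between members. PSG6, a pregnancy-specific glycoprotein gene, fell by 5.18 ± 0.16, MANCR, a long noncoding RNA gene (ENSG00000231298, chromosome 10, 4650185 to 4678154), by 4.43 ± 0.10, and CLDN2 to 10 counts over the 6 libraries. MIR138-1, a microRNA gene, had 1 count over the 6 combination libraries against 520 in control, a ratio of 0.00176 (95% counting interval 4.44e-05 to 0.00984, which covers counting error alone, since the reads carry no molecular tags that would separate PCR copies).

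Genes of DNA replication rose again in the combination: 35 of 38 rose and 0 fell, 25 of them at least 2-fold, with a median of 1.28 (adjusted p = 1.8e-05 with an estimated correlation). CDC6 rose by 2.78 ± 0.07 and ORC1 by 1.99 ± 0.05. In autophagy and lysosome 21 of 28 rose and 2 fell (adjusted p = 0.0083 with an estimated correlation), with ATP6V1H, a subunit of the lysosomal proton pump, at 0.69 ± 0.05. The other 9 lists past the threshold with the preset correlation were not past it with an estimated one. Of these, all 5 metallothionein and metal-induced genes rose (adjusted p = 0.053 with an estimated correlation), with a median of 2.26 and MT1G at least 39.9-fold higher against the same floor. Of 38 ribosomal protein genes 33 rose and 0 fell (adjusted p = 0.39 with an estimated correlation). In ATR-CHK1 signalling 16 of 22 rose and 3 fell (adjusted p = 0.21 with an estimated correlation), with CHEK1 at 1.85 ± 0.15 and ATR at -0.47 ± 0.12. In heat shock 15 of 21 rose and 3 fell (adjusted p = 0.17 with an estimated correlation), with the HSP40 gene DNAJB1 at 2.77 ± 0.09. In G2/M and mitosis 21 of 32 rose and 3 fell (adjusted p = 0.42 with an estimated correlation). Of 43 nuclear-encoded respiratory chain genes 25 rose and 2 fell (adjusted p = 0.33 with an estimated correlation), with COX6A1 at 1.07 ± 0.07.

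Other lists moved down or both ways in the combination. Of the mitochondrial mRNAs 10 of 13 fell and 2 rose (adjusted p = 0.20 with an estimated correlation), with MT-CO1 at -1.26 ± 0.04 and MT-ND6 at -2.95 ± 0.13. The mitochondrial share of counts was 2.65% ± 0.14, lower than in control by 1.80 points, with all 6 libraries below all 6 controls (exact permutation test, two-sided, n = 6 each, p = 0.00216, the smallest possible, adjusted p = 0.00325). Of 23 NF-kB targets and cytokines 13 fell and 5 rose (adjusted p = 0.28 with an estimated correlation), with the cytokine genes IL1B and LIF at -1.85 ± 0.09 and -2.04 ± 0.13. Of 29 homologous recombination genes 16 rose and 6 fell, just past the threshold with the preset correlation (adjusted p = 0.0498) and not with an estimated one (adjusted p = 0.54). The preset result of this list was lost, with adjusted p values of 0.0503 to 0.0693, when any of control replicates 1 and 4, elesclomol replicates 4, 5 and 6, olaparib replicates 2 and 3 or combination replicates 1, 3, 4, 5 and 6 was left out. That of the NF-kB list was lost without control replicate 1 or 4 or combination replicate 3 or 4, with 0.0502 to 0.0575. EXO1, a nuclease gene of DNA end resection, rose by 2.40 ± 0.11, and RAD50, of the complex that senses double-strand breaks, fell by 2.66 ± 0.15. CDKN1A rose by 1.86 ± 0.12, ABCB1 by 1.56 ± 0.13 and FDX1, the ferredoxin gene of protein lipoylation, by 0.82 ± 0.05.

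In total 5816 genes were higher and 5901 lower in the combination, of which 1641 and 2906 changed at least 2-fold. Adjusted over the list alone, 35 DNA replication and 33 ribosomal protein genes rose. With upper-quartile scaling the median of all genes shifted to -0.16 and the share of called genes that were higher went from 49.6% to 39.3%. The balance of higher and lower genes is therefore relative to the scaling, while the medians of the lists past the threshold kept their sign with it.

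**Figure D3:**
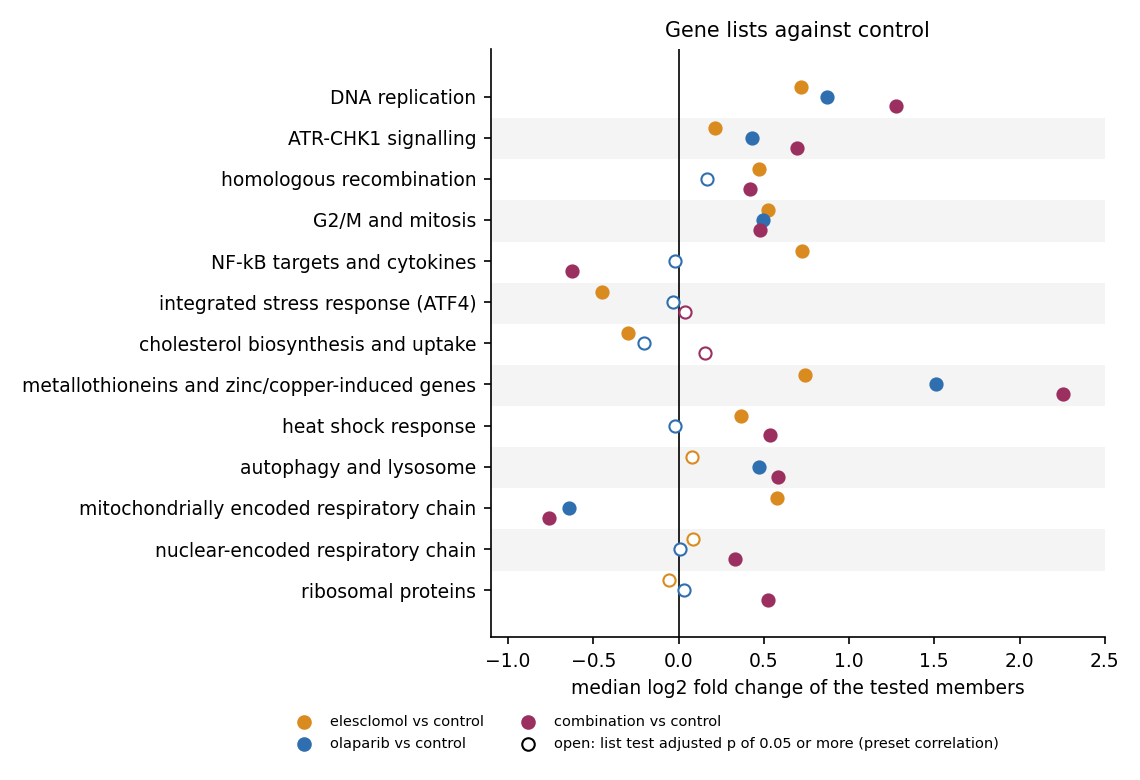
Each point is the median log2 fold change of the tested members of a gene list against control, coloured by drug group, and it is open where the list was not past the threshold with the preset correlation. The DNA replication medians are 0.72 with elesclomol, 0.87 with olaparib and 1.28 in the combination.

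Some lists bearing on the drugs were not past the threshold in any comparison with control. In the combination, 8 of 17 copper handling genes rose and 6 fell (adjusted p = 0.72), with MTF1, the metal-responsive transcription factor, at 0.83 ± 0.05. Of 14 genes of protein lipoylation and its target enzymes, 7 rose and 3 fell (adjusted p = 0.26). Of 24 genes of the PARP family and base excision repair, 8 rose and 7 fell (adjusted p = 0.85), with PARP1 at 0.78 ± 0.04; with upper-quartile scaling 5 rose and 11 fell. Of 20 genes of non-homologous end joining and the 53BP1-shieldin axis, 6 rose and 6 fell (adjusted p = 0.51), with TP53BP1 at -0.41 ± 0.04. With elesclomol 9 of them rose and 1 fell, and without the 2 libraries that stood apart this list passed there (adjusted p = 0.0384). Of 23 p53 target genes 12 rose and 4 fell (adjusted p = 0.21), and of 13 ABC drug transporter genes 3 rose and 7 fell (adjusted p = 0.26). Of 22 endoplasmic reticulum chaperone genes 13 rose and 2 fell (adjusted p = 0.12), and of 23 genes of the NRF2 oxidative stress response 12 rose and 4 fell (adjusted p = 0.088), with NQO1, a quinone reductase gene, at 1.18 ± 0.05. HMOX1, the haem oxygenase gene, rose by 0.67 ± 0.18. Of 24 apoptosis regulators 9 rose and 6 fell (adjusted p = 0.41), of 32 hypoxia and glycolysis genes 11 rose and 7 fell (adjusted p = 0.51; 7 and 12 with upper-quartile scaling, and the list passed with olaparib under the GC covariate, at 0.0397), and of 27 interferon-stimulated genes 9 rose and 10 fell (adjusted p = 0.71). Of 14 epithelial genes 2 rose and 6 fell (adjusted p = 0.51). Of 4 tested endothelial markers 1 rose and 2 fell (adjusted p = 0.51). The one that rose, TIE1, was lost with upper-quartile scaling (adjusted p = 0.190), without combination replicate 2 (0.130) and without control replicate 2, 5 or 6 (0.0544, 0.0570 and 0.0587). Only 2 haematopoietic markers were tested, too few for a list test, and neither call was firm. CSF1R was higher, but not with DESeq2 (0.0654), upper-quartile scaling (0.127), no filter (0.0637), without the 2 libraries that stood apart (0.0668), or without control replicate 1, 2, 5 or 6 or combination replicate 1, 2 or 5 (0.0516 to 0.115). FCER1G was lower, but not with no filter (0.0616) or without control replicate 2 (0.0540) or combination replicate 3 (0.0773). For every list past the threshold in any comparison the median, the mean and the test had the same sign, while for 4 of the 32 lists tested in the combination against control they differed in sign.

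The comparison of the combination with elesclomol describes what olaparib added to elesclomol only if doses and durations were the same, which the labels do not say. CXCL1, a chemokine gene, fell by 3.66 ± 0.10 (adjusted p = 1.8e-19), the cytokine genes IL1B and IL24 fell by 2.61 ± 0.09 and 3.82 ± 0.14, and MANCR fell by 5.04 ± 0.10. FOS, an immediate-early transcription factor gene, rose by 4.51 ± 0.17 (adjusted p = 1.1e-16). Of 23 NF-kB targets and cytokines 15 fell and 2 rose, and of the 13 mitochondrial mRNAs 12 fell and 0 rose, each with an adjusted p = 0.0069 with an estimated correlation. MT-CO1 and MT-ND5 fell by 1.79 ± 0.04 and 2.17 ± 0.06. In autophagy and lysosome 21 of 28 rose and 1 fell (adjusted p = 0.0069 with an estimated correlation), and of 38 DNA replication genes 29 rose and 3 fell (adjusted p = 0.030 with an estimated correlation). Ribosomal proteins (34 of 38 rose and 0 fell), metallothioneins (4 of 5 rose), cholesterol synthesis and uptake (18 of 26 rose and 4 fell), MAPK and AP-1 genes (15 of 24 rose and 6 fell) and the integrated stress response (16 of 27 rose and 7 fell) passed with the preset correlation alone. With an estimated correlation their adjusted p values were 0.355, 0.092, 0.058, 0.43 and 0.42. The integrated stress response was also lost without elesclomol replicate 1 (adjusted p = 0.0503). In total 5555 genes were higher and 5687 lower, of which 1419 and 2628 changed at least 2-fold. Upper-quartile scaling shifted the median of all genes to -0.13. For DNA replication adjusted over the list alone, 29 genes rose and 3 fell.

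The comparison of the combination with olaparib describes what elesclomol added to olaparib, on the same condition of equal doses and durations. TFRC rose by 3.44 ± 0.07 (adjusted p = 5.2e-21) and HSPA6, a strictly inducible HSP70 gene, by 5.16 ± 0.41 (adjusted p = 5.3e-10). CLDN2 fell from 1258 counts over the 6 olaparib libraries to 10 in the combination, and KRT5, a basal keratin gene, from 499 to 4. CDKN1A fell by 0.88 ± 0.11 and IL24 by 2.06 ± 0.14. SNORD14E, a small nucleolar RNA gene inside HSPA8 on the same strand (ENSG00000200879, chromosome 11, 123058077 to 123058161), rose by 5.65 ± 0.22, and its reads could not be separated from those of the host transcript.

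In the same comparison several lists of protein synthesis, respiration and metal handling rose. DNA replication rose in 24 of 38 genes and fell in 0 (adjusted p = 0.0022 with an estimated correlation), with CDC6 at 1.03 ± 0.06. Of 21 heat shock genes 12 rose and 1 fell (adjusted p = 0.0031 with an estimated correlation). Of 23 genes of iron-sulfur clusters and iron handling 10 rose and 1 fell (adjusted p = 7.9e-04 with an estimated correlation), with SLC11A2, an iron importer, at 0.79 ± 0.06. Of 19 ferroptosis regulators 9 rose and 2 fell (adjusted p = 0.0014 with an estimated correlation), with the fatty acid desaturase gene SCD at 0.78 ± 0.04; TFRC is in both of these lists. Of 43 nuclear-encoded respiratory chain genes 26 rose and 0 fell (adjusted p = 0.019 with an estimated correlation), with NDUFA4 at 0.67 ± 0.05. Of 26 cholesterol genes 13 rose and 1 fell (adjusted p = 0.023 with an estimated correlation), with INSIG1 at 0.95 ± 0.07. All 5 metallothionein and metal-induced genes rose (adjusted p = 0.026 with an estimated correlation), with MT1X at 2.36 ± 0.15. Of 38 ribosomal protein genes 33 rose and 0 fell (adjusted p = 0.044 with an estimated correlation), with RPL23 at 0.69 ± 0.05. The mitochondrial mRNAs moved apart, with 6 of 13 lower and 3 higher (adjusted p = 0.20 with an estimated correlation): MT-CO1 fell by 1.84 ± 0.04 and MT-ND2 rose by 1.78 ± 0.08. NF-kB targets (2 of 23 rose and 11 fell) and the NRF2 list (7 of 23 rose and 1 fell) passed with the preset correlation alone, with adjusted p values of 0.12 and 0.057 with an estimated correlation. The NRF2 list was also lost without combination replicate 5 (adjusted p = 0.0612). In total 3332 genes were higher and 3928 lower, of which 195 and 1045 changed at least 2-fold. The share of called genes that were higher, 45.9%, was 36.8% with upper-quartile scaling and thus relative to the scaling. With the GC covariate, chosen after the data were seen, 5624 were higher and 5486 lower, so the excess of lower genes among all calls was not kept. Whether the excess among changes of at least 2-fold was kept was not examined. For DNA replication, 24 genes rose adjusted over the list alone.

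**Figure D4:**
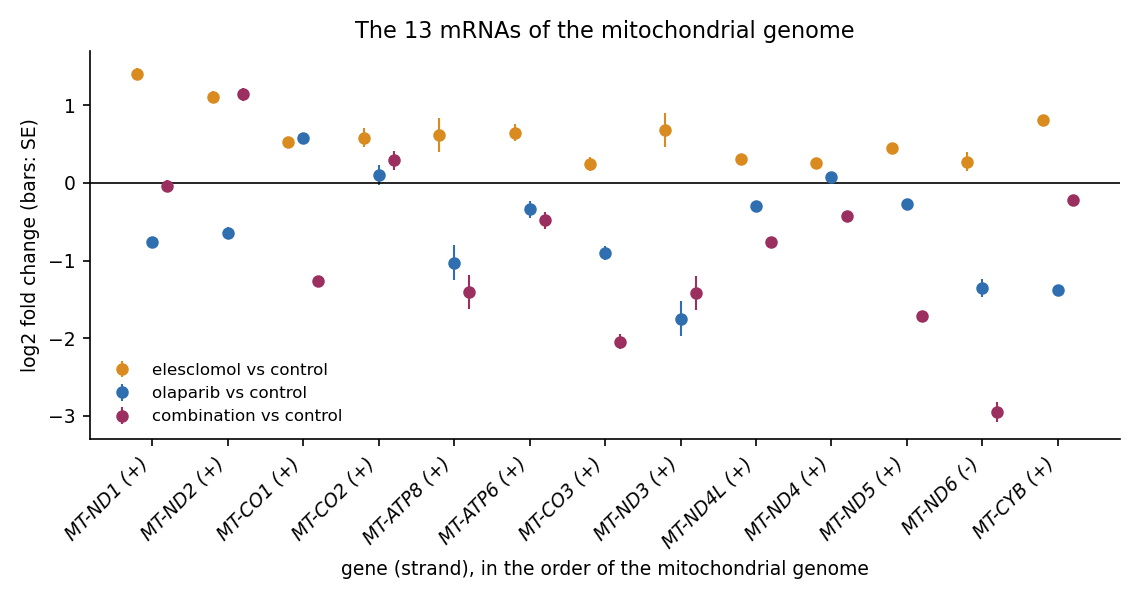
Each point is the log2 fold change against control of 1 of the 13 mRNAs of the mitochondrial genome, in the order of the genome, with its SE as a bar and the drug group as its colour. MT-CO1 is at 0.53 with elesclomol, 0.58 with olaparib and -1.26 in the combination, while MT-ND2 is at 1.10, -0.64 and 1.14.

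Elesclomol compared directly with olaparib differed in 5242 genes that were higher with elesclomol and 5337 that were lower. ESM1 was higher by 4.98 ± 0.07 (adjusted p = 1.7e-25), CXCL1 and CXCL8 by 3.78 ± 0.10 and 3.87 ± 0.17, and COL6A3, a collagen gene, by 2.29 ± 0.07. PTGES was lower by a log2 change of -4.49 ± 0.22, BMF, a pro-apoptotic BH3-only gene, by -3.12 ± 0.14 and CDKN1A by -2.53 ± 0.12. KRT5 and CLDN2 had 3 and 9 counts over the elesclomol libraries and 499 and 1258 over the olaparib libraries. Of the 13 mitochondrial mRNAs 12 were higher and 0 lower, and of 23 NF-kB targets and cytokines 15 were higher and 5 lower (each adjusted p = 0.041 with an estimated correlation). The integrated stress response (5 of 27 higher and 18 lower) passed with the preset correlation alone (adjusted p = 0.53 with an estimated correlation). These were the 3 lists past the threshold, and 5 lists passed without olaparib replicate 1 or without olaparib replicate 2. Of the mitochondrial mRNAs 12 were higher adjusted over the list alone.

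The interaction asks where the combination differed from the sum of the log2 changes of the single drugs, or equally where the elesclomol change with olaparib differed from that without. Unequal doses or durations, which the labels do not exclude, would also enter the interaction. The interaction was negative for IL24 at -3.93 ± 0.18 (ENSG00000162892, chromosome 1, 206897443 to 206904139; adjusted p = 1.5e-13): its level was 4.55 ± 0.41 CPM in control, 16.6 ± 1.26 with elesclomol, 4.87 ± 0.70 with olaparib and 1.20 ± 0.40 in the combination. CXCL1 and TNFAIP3 had interactions of -2.33 ± 0.13 and -1.97 ± 0.11. It was positive for the immediate-early genes EGR1 at 3.19 ± 0.22 and FOS at 2.87 ± 0.23 (ENSG00000170345, chromosome 14, 75278774 to 75282230); FOS went from 5.80 ± 1.34 CPM in control to 4.47 ± 0.33 with elesclomol, 18.1 ± 5.15 with olaparib and 102 ± 16.9 in the combination. SCD, TFRC and HSPA1A had positive interactions of 1.69 ± 0.06, 0.99 ± 0.09 and 2.21 ± 0.33. BRCA1 and CDKN1A had negative ones, -1.19 ± 0.18 and -1.08 ± 0.17. For ATR and CHEK1 no interaction was called, at -0.21 ± 0.16 and 0.05 ± 0.21, but with the GC covariate that of ATR was (adjusted p = 0.0028).

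Of 23 NF-kB targets and cytokines the interaction was negative in 14 and positive in 2 (adjusted p = 1.6e-04 with an estimated correlation), and of 26 cholesterol genes it was positive in 18 and negative in 2 (adjusted p = 1.6e-04 with an estimated correlation), led by FDFT1 at 1.14 ± 0.06 and INSIG1 at 1.54 ± 0.10. Of the 13 mitochondrial mRNAs it was negative in 9 and positive in 2 (adjusted p = 0.0011 with an estimated correlation), with MT-CO1 at -2.37 ± 0.06. Of 19 ferroptosis regulators it was positive in 5 and negative in 1 (adjusted p = 0.0026 with an estimated correlation), and of 23 iron-sulfur and iron handling genes positive in 8 and negative in 2 (adjusted p = 0.0043 with an estimated correlation). Of 38 DNA replication genes it was negative in 21 and positive in 2 (adjusted p = 0.012 with an estimated correlation), with GINS2 and MCM10 at -0.83 ± 0.09 and -1.22 ± 0.13, so the combined rise of this list was smaller than the sum of the single-drug rises. The other 9 lists past the threshold were not past it with an estimated correlation. Ribosomal proteins (positive in 31 of 38), nuclear-encoded respiratory chain genes (17 of 43), the integrated stress response (14 of 27, negative in 2), antigen presentation (5 of 17, negative in 1), heat shock (9 of 21, negative in 4) and MAPK and AP-1 genes (9 of 24, negative in 4) had adjusted p values of 0.051, 0.090, 0.11, 0.19, 0.20 and 0.35 with an estimated correlation. G2/M and mitosis (negative in 19 of 32), homologous recombination (13 of 29, positive in 2) and ATR-CHK1 signalling (10 of 22, positive in 3) had 0.092, 0.36 and 0.36. Antigen presentation was also lost without olaparib replicate 1 (adjusted p = 0.0513) and heat shock without combination replicate 5 (adjusted p = 0.0634). In total the interaction was positive in 2249 genes and negative in 2960, of which 306 and 1012 reached a log2 size of 1. With a covariate for GC content, chosen after the data were seen, it was positive in 4585 and negative in 4774. Among all calls neither the number nor the excess of negative genes is therefore firm. Whether the excess at a log2 size of 1 was kept was not examined. Adjusted over the list alone, it was negative in 22 DNA replication genes and positive in 2. In simulated data with known changes 8.41% of the interaction calls were false, against 6.49% for elesclomol with control. Those genes varied independently, so the shares need not hold for the data.

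The single-drug changes overlapped in part. Of the genes called both with elesclomol and with olaparib against control, 2987 changed in the same direction, 1416 up and 1571 down, and 1398 in opposite directions. Independent calls would give 976 up and 964 down. Because both comparisons used the same control libraries, the count was repeated with the controls split between them, 3 for each comparison. At the median of 20 splits 2101 genes then changed in the same direction (range 2072 to 2302) and 977.5 in opposite directions. The values for independent calls belong to the full comparisons and cannot be set against the count of the splits. In 20 simulations that redrew all libraries at the control means, without drug effects, it was 0. Where no gene is changed few calls can be made, so this does not show how far shared controls raise the count. Across genes the correlation of the changes was 0.265. With the controls split, so that none were shared, its median was 0.226 (range 0.189 to 0.256). The covariance was 0.117, at the median 0.105 in the splits and 0.0171 in the simulations without drug effects. These values argue against shared controls as the whole cause of the correlation. The simulated correlation was 0.518, but it goes with a far smaller covariance and cannot be set against 0.265. Genes are not independent replicates. TFRC and CXCL8, chosen for olaparib after their values were seen, are examples of genes not called in the same direction: TFRC was at 0.09 ± 0.07 with olaparib, and CXCL8 fell by 1.45 ± 0.16. The elesclomol change with olaparib and that without were in the same direction in 2381 called genes and in opposite directions in 851, and the olaparib change with and without elesclomol in 8166 and 502.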

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

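The tests of GC content bias and library depth for the 2 libraries that stand apart and those with a GC covariate were chosen after the result was seen. So was the argument on normalization for the mitochondrial transcripts. The same holds for the choice to let only markers no higher in control than the highest gene of the pattern argue against cells of another type. A library was singled out where its gap to the nearest of the other 5 of its group was a large part of the range of the group. This was tested for 26 measures in 4 groups, 104 in all, and 13 were singled out; chance gives about 1 in 20, or 5.2. Combination replicate 2 was singled out in most of them, and olaparib replicate 6 in the others but 1. The exception was the total count of control replicate 6, 20280162 against 16141920 to 17651475 in the rest, with a gap of 0.6352 of the range.

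The share of counts in the 100 largest genes was 30.3% in olaparib replicate 6 (25.4% to 27.2% in the rest of the group, gap 0.643) and 33.1% in combination replicate 2 (26.6% to 28.1%, gap 0.7692). Combination replicate 2 also had a TMM factor of 0.748 (0.911 to 0.961, gap 0.7663) and the highest slope of expression on GC content in its group, 0.4415 log2 per 10 percentage points (-0.1794 to -0.0788, gap 0.8379). In the same library the level of TFRC was 531.5 CPM (697.6 to 733.3, gap 0.8231), that of CXCL8 10.9 CPM (20.4 to 25.2, gap 0.6638), that of EGR1 707.8 CPM (395 to 480.4, gap 0.727), that of ATR 27.2 CPM (42.2 to 51.1, gap 0.6288) and that of GDF15 81.3 CPM (38.3 to 42.4, gap 0.9043). In olaparib replicate 6 the level of ESM1 was 12.8 CPM (9.68 to 10.7, gap 0.6646), that of EGR1 185 CPM (95.6 to 128.1, gap 0.6369) and that of GDF15 136.4 CPM (40.4 to 75.5, gap 0.6346).

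Olaparib replicate 6 and combination replicate 2 lay far from the means of their groups. A swap with another group was argued against, since 0 of the 2 lay nearest to the mean of another group. GC content bias may have contributed: the slope of the deviation from the group mean on GC content was 0.4405 and 0.4635 log2 per 10 percentage points, outside the range of the other 22 libraries (-0.1986 to 0.2002) for 2 of the 2. Library depth may also have contributed, since 2 of the 2 had the lowest total of their group, 14793908 and 16127234. Control replicate 1 and elesclomol replicate 6, with totals of 16141920 and 16236364, lay only 0.307 and 0.260 from the means of their groups. For combination replicate 2 this argues against depth as the whole cause. Both stay open as contributions, as does a difference in the cells or the RNA, which was not tested.

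Some changes with elesclomol differed between cells with and without olaparib, by a test of the difference itself. For the single genes named by the rule, which asks for a mean CPM of at least 2, the differences were 5.47 ± 0.65 for SNORD14E (adjusted p = 6.5e-07), 3.19 ± 0.22 for EGR1, 3.0 ± 0.63 for HSPA6 (adjusted p = 5.4e-04), 2.87 ± 0.23 for FOS, -3.93 ± 0.18 for IL24, -3.30 ± 0.34 for KCTD4, -3.28 ± 0.98 for MIR138-1 (adjusted p = 0.0025) and -2.72 ± 0.28 for the keratin-associated gene KRTAP4-9. The median differences of lists past the threshold with both correlations were 0.30 for iron-sulfur clusters and iron handling, -0.42 for DNA replication, -0.89 for NF-kB targets and cytokines, 0.68 for cholesterol biosynthesis and uptake, -0.78 for the mitochondrially encoded respiratory chain and 0.37 for ferroptosis regulators.

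Between the combination and olaparib the mitochondrial mRNAs moved apart, with MT-ND2 higher and MT-CO1 lower. Normalization alone was argued against by the pattern itself, since a scaling factor moves all members alike. Here 3 members were called higher and 6 lower. That count restates the pattern and is no separate test. Reads shared with nuclear copies were argued against, since the summed CPM of MT-CO1 and its 12 nuclear copies changed by -1.84. The mean slope of expression on GC content was 0.0211 ± 0.249 with olaparib and -0.0220 ± 0.231 in the combination (SD, n = 6). Such close means argue against a linear GC bias as the whole cause. With the GC covariate, taken from the same expression values, the gap between MT-ND2 and MT-CO1 was 3.61, against 3.62 without. Since the slopes were so close, the covariate could hardly move the gap, and it cannot decide on GC bias of another form. In 0 of the 24 fits that left out 1 library did either gene lose its call or turn. An effect of elesclomol in cells with olaparib on single mitochondrial transcripts is a candidate explanation and remains a hypothesis.

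With elesclomol against control and with the combination against olaparib 11 genes were lower by a log2 change of at least 2.5 in size, a limit chosen after the data were seen, and 1 was higher by as much. They are CLDN2, KRT5, KRT19, MAGEA4, MUC5AC, MUC5B, MUC6, MRPL23-AS1, PADI2, TDRD12 and ENSG00000266976, most of them chosen after their values were seen; PADI2, with 0 counts in the combination, was at least 58.3-fold lower there than with olaparib against the floor. A single library as the cause was argued against by 0 of 24 fits in which a gene of the pattern lost a call or turned. For loss of a chromosome segment around the 3 mucin genes on chromosome 11, the 50 neighbouring genes within 1 Mb had median changes of -0.127 and 0.0291. This argues against loss of the whole window, but a loss limited to the mucin genes would not move these medians. Of the neighbours 7 were lower in both comparisons, among them MRPL23-AS1. For loss of cells of another type, 1 of the 6 epithelial genes at 2 CPM or more in control fell in both comparisons. This is fewer than the explanation was held to need beforehand. The gene was CLDN4, at 10.1 CPM. Its call in the second comparison was lost with only the 2 groups in the fit, without olaparib replicate 6 and without combination replicate 1, 3 or 4, at adjusted p values of 0.0535 to 0.0871. JUP and WT1, at 2.82 and 2.44 CPM, were not called (0.30 and 0.53, and -0.16 and 0.17). In control they were lower than CLDN2, at 4.96 CPM, but higher than KRT5, at 2.25 CPM, and all other genes of the pattern. KRT7, KRT18 and KRT8 at 285.6, 133.7 and 53.9 CPM would hide a small share. Epithelial genes under 2 CPM in control were left out. With only 2 markers no higher than CLDN2, loss of cells of another type may still hold, as may silencing of these genes with elesclomol, and the 2 cannot be told apart.

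Random regroupings of the libraries, 100 for each comparison with the real one included, were used to ask whether chance could give as many genes or lists. For genes the real number was the highest in each comparison, which argues against an arbitrary split of these libraries. Chance differences between cultures are not covered, since nothing says that the replicates are separate cultures. For the interaction the regroupings also mix the single-drug effects, so they do not test the interaction alone. Only 1 of the 100, the real one, reached 5765 with elesclomol against control (highest other 1874), 10704 with olaparib (7531) and 11717 in the combination (7964). The same held for 11242 in the combination against elesclomol (7638), 7260 in the combination against olaparib (4991), 10579 for elesclomol against olaparib (6561) and 5209 for the interaction (2404). For lists the regroupings cannot decide, since many leave unequal shares of the groups on each side and still hold part of the drug difference. With elesclomol against control 65 of the 99 others passed some list, though their median number of genes called was 0. The 15 lists of the interaction were reached by 2 regroupings (highest other 15). The real numbers of the other comparisons were reached more often. They were 12 with elesclomol against control (reached by 19, highest other 14), 6 with olaparib (by 28, 9) and 11 in the combination (by 11, 14). In the combination against elesclomol the number was 9 (by 42, 12), against olaparib 11 (by 11, 14), and for elesclomol against olaparib 3 (by 47, 11).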

How the results depend on the processing

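The GC covariate and the fit without the 2 libraries that stood apart were chosen after the result was seen; the other alternatives were fixed before the data were examined. No called named gene and no list past the threshold turned its direction in an alternative. With upper-quartile scaling 2 of the genes called in the combination against control were called in the opposite direction. Medians of several lists not past the threshold did turn with it. In the combination against control that of protein lipoylation went from 0.14 to -0.03, and that of hypoxia and glycolysis from 0.06 to -0.11, with 7 genes higher and 12 lower. Among the others that turned there, the integrated stress response went from 0.04 to -0.13. The mesenchymal and extracellular matrix list went from 0.07 to -0.10, with 9 genes higher and 13 lower. Of lists past the threshold, the heat shock genes that rose with elesclomol went from 14 to 9 with it, and the few members that fell among lists that rose became more: in autophagy and lysosome from 2 to 4 in the combination and from 1 to 4 against elesclomol, in nuclear-encoded respiratory chain genes from 2 to 4 in the combination, in G2/M and mitosis from 2 to 4 with olaparib and from 3 to 5 in the combination, and in ATR-CHK1 signalling from 1 to 4 with olaparib. Of 854 values of named genes, taken over the alternatives, 28614 kept direction and side of the threshold, 143 lost their call and 88 gained one. Of 224 values of lists, 6609 kept both, 70 lost their call, 35 of them with an estimated correlation, and 41 gained one. DESeq2, limma-voom, RLE and upper-quartile scaling, either filter, the fit of only the compared groups and the replicate block kept every number of genes within 1.5 times its value.

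With an estimated correlation the number of lists past the threshold fell to 1 with olaparib, 2 in the combination, 4 in the combination against elesclomol and 6 for the interaction; the cause was not tested. With the GC covariate 4899 genes were higher and 4746 lower with elesclomol, 5624 were higher in the combination than with olaparib, and the interaction was positive in 4585 and negative in 4774; the cause was not tested. Without the 2 libraries 3845 genes were higher and 3953 lower with elesclomol. With each library left out in turn the number of lists for elesclomol against olaparib ranged from 3 to 5; the cause was not tested.

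The overlap of calls in the same direction was 3136 with DESeq2 and 2816 with the replicate block. Replicate numbers did not pair libraries of different groups: in 8 of 36 cases a library correlated best with the one of its own number. The mitochondrial share from protein-coding genes alone was 4.63% with elesclomol, 3.22% with olaparib, 1.87% in the combination and 3.33% in control. The alternatives written for a table that holds only FPKM, the pseudocount and a filter on low values, were not run, as counts were deposited. The low counts of CLDN2, KRT5, MIR138-1 and MT1G limit their folds.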

Other observations

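All of the values on histone genes below were chosen after the result was seen. Among the replication-dependent histone genes of the clusters on chromosomes 6 and 1 and elsewhere, 28 were tested, 19 of them on chromosome 6 and 7 on chromosome 1. In the combination against control 27 rose, 26 of them at least 2-fold, and 1, H4C16, fell, with a median of 3.65 and a range of -2.83 to 5.41. With elesclomol 14 rose and 0 fell, with a median of 0.61, and with olaparib 16 rose and 1 fell, with a median of 1.13. Against olaparib the combination had 26 higher and 0 lower, with a median of 2.20, and the interaction was positive in 15 and negative in 0. The level of H2BC12 was 8.04 CPM in control, 17.9 with elesclomol, 24.6 with olaparib and 58.3 in the combination. This was the highest control level of the histone genes tested. Most of the others were under 1 CPM in control, so their folds start from few counts. H2BC8, with the largest change of 5.41, went from 0.0780 CPM in control to 3.64 in the combination. Reads of these near-identical genes are hard to assign to single members, and no explanation was tested.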
